A study of Mus musculus with 2 samples.

How the data were processed

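Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on mouse neural progenitor cells that had been differentiated from embryonic stem cells of C57BL/6 background. 1 library was made with an antibody against Tet3 and 1 from input DNA, which is sheared chromatin taken without antibody. Per the labels' protocols, chromatin was sheared with a Covaris kit and the fragment libraries were sequenced on the SOLiD platform, which reads short fragments in colour space. The submitters' processing notes name Bowtie, a short-read aligner, MACS, a peak caller, and the genome build mm9. Versions, mapping filters, duplicate handling and peak-calling thresholds are not given in the sources used here.

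Each library has a deposited list of peaks with chromosome, start, end, an identifier and a score. Per the file contents, all identifiers have the form that MACS writes. The deposited score of a peak is the authors' own value from the caller. No header defines it, so its form was tested on the values. For each list, 1 background rate was sought at which the score equals minus 10 times the decimal logarithm of a Poisson tail, the chance of more than a whole number of reads given that rate times the peak width. Matching within 0.01, 22.8% of Tet3 scores and 55.6% of Input scores had this form, against medians of 0.293% and 0.288% at other rates. The remaining scores can follow a higher local background, which MACS uses where it exceeds the genome-wide one. The lowest scores are 50 and 50.01. Scores were used to rank and filter peaks within 1 list, and the matching ones to recover the number of reads behind a peak. On simulated lists of 347 and 3412 peaks, the same procedure returned 45.2% and 51.2% matching scores where 45.0% and 51.2% had been made so, with 100% of their read numbers right. The simulated scores were made with the same formula, over a narrower range of widths and read numbers than in the Tet3 list. This checks the fitting and not whether the caller's scores have that form. The deposited start and end positions are the other values used, and starts are given here counted from 1. It is not stated whether the Input library served as control for the Tet3 call, or which control the Input call had. Each list belongs to 1 library, and neither source says that samples were pooled. Neither list states the reads per library, so total depth is unknown, and the intervals given here rest on the number of peaks.

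From these lists, peak counts, widths and scores were summarised with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The figures were drawn with matplotlib 3.10.9. Overlaps of at least 1 bp were counted with bedtools 2.31.1. Chromosome lengths of mm9 were not used here. The span from the first to the last peak of either list stood in for the length of each chromosome, which leaves the chromosome ends out of the densities. Peaks lying within 10 kb of the previous peak were joined into clusters. As a background, the peaks of a list were placed 1000 times at uniform random positions within the span of their own chromosome, keeping their widths. The central 95% of these placements is given beside each observed value. Placement ignored assembly gaps, mappability and gene density, so a departure from it describes the list and does not identify a cause. Intervals are 95% and exact: Clopper-Pearson for shares, Poisson for counts, and order statistics for medians. For a count of 0 the limit is 3 counts, a one-sided bound. All of these cover counting error over peaks only. With 1 library per group there is no replicate error, so no p-value between Tet3 ChIP and Input is given. On simulated lists of 3400 peaks, 300 of 300 planted neighbour pairs and 100 of 100 planted overlaps were recovered, and 94 of 100 uniform lists fell within the 95% range of 200 random placements.

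The regions named in the text were chosen by a rule fixed before the data were examined. These are the 10 highest-scoring Tet3 peaks without an overlapping Input peak, up to 3 with one, the 5 highest-scoring Input peaks, and the 3 clusters with most Tet3 peaks, ties going to the cluster with the highest-scoring peak. Regions named for their number of peaks per 5 Mb window, and the peaks named on the X chromosome, were chosen after their values were seen. Alternatives were the higher-scoring 50% of each list, other overlap and cluster distances, autosomes alone, and Tet3 peaks without Input overlap. Leaving out chromosome 8, leaving out regions on chromosomes 9, 2 and 17, and a score threshold of 60 were added after seeing the data. So were the pooled spread over the 18 other autosomes and the share in the densest windows, each set against 200 placements.

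An mm9 gene annotation and genome sequence were not used here. The gene table at hand is of GRCm38, and 35 peaks on 8 chromosomes end beyond the last gene it lists, so its positions were not combined with the peaks. For that reason the planned promoter shares, genes at peaks, and 14 fixed gene lists were not analysed here. This includes Sfrp4 and the Tet genes, which the rule would have reported.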

Results

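Binding of Tet3 across the genome was profiled in mouse neural progenitor cells derived from embryonic stem cells. Tet3 belongs to the TET dioxygenases, which oxidise methylated cytosine in DNA. The study as a whole concerns TET proteins, Wnt signalling and the choice between neuroectoderm and cardiac mesoderm, and this part of it asked where in the genome Tet3 sits in neural progenitors. The data comprise 2 peak lists on mm9, each called on 1 library. The list from the Tet3 ChIP held 3412 peaks and the list from Input DNA, which received no antibody, held 347. There were no replicates, so every difference below compares these 2 libraries and has no replicate check.

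The Tet3 library yielded 9.83 times as many peaks as Input, and its peaks covered 2948 kb against 201 kb, a ratio of 14.7. Tet3 peaks were wider, with a median width of 740 bp (95% interval 729 to 750) against 569 bp (552 to 583) in Input. Of the Tet3 peaks, 26.5% (exact binomial 95% interval 24.99 to 27.98) were wider than 1000 bp, against 0.576% (0.0699 to 2.07) of Input peaks. Width went with the caller's score in the Tet3 list, with a Spearman correlation of 0.48 across peaks, and much less so in the Input list, where it was 0.10. Peaks of 1 library are not independent replicates, so these correlations describe the lists. In the Tet3 list 464 peaks scored above 100 and 26 above 200, whereas the highest Input score was 95.96. If the score has the Poisson form described above, the number of reads behind a peak can be recovered for part of each list. In the 193 Input peaks whose score matched a genome-wide Poisson background, the recovered number of reads had a median of 10 (quartiles 9 and 11). In the 778 matching Tet3 peaks, 22.8% of the list, the median was 12 (quartiles 11 and 15), and no read number was recovered for the rest. The background rates were 3.05 reads per kb in the Input call and 4.05 in the Tet3 call. Total read depth and the control used in each call are unknown, and both affect how many peaks a caller reports and how wide they are.

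**Figure D1:**
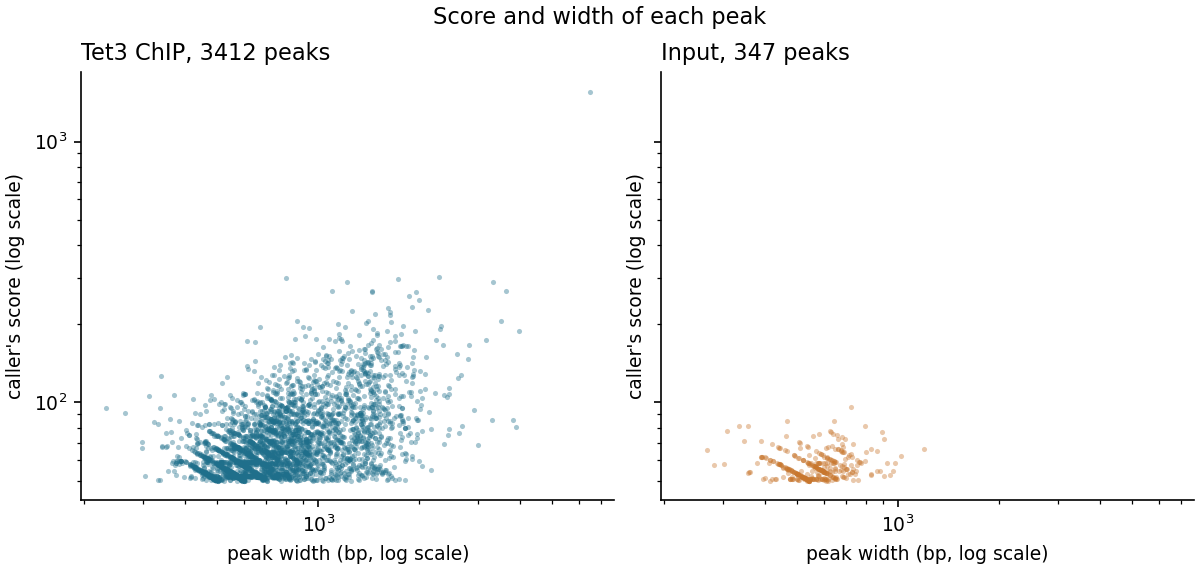
Width in bp (x axis, log scale) and the caller's score (y axis, log scale) of each peak, 1 point per peak, for 3412 Tet3 ChIP peaks (left) and 347 Input peaks (right). Tet3 peaks extend to 6464 bp and a score of 1552, and Input peaks stop at 1192 bp and 95.96.

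The highest-scoring Tet3 peak lay on chromosome 17 at 39979475 to 39985938. It was also the widest, at 6464 bp, and its score of 1552 was far above the next value, 303.59. That second peak lay on chromosome 8 at 125243030 to 125245324, and the fourth lay on the same chromosome at 123276645 to 123278379 with a score of 297.45. A stretch of chromosome 2 held 3 of the 10 highest-scoring peaks. These were at 98503624 to 98504422 (score 300.57), 98502217 to 98503318 (268.33) and 98506223 to 98507665 (267.35). Chromosome 9 contributed a peak at 3035546 to 3036760 (score 289.79), within the first cluster of peaks on that chromosome, and one at 119425640 to 119429261 (267.91), which was 3622 bp wide. The remaining peaks of the 10 were at 16865360 to 16868671 on chromosome 7, with a score of 289.85, and at 126736164 to 126737607 on chromosome 10, with a score of 264.85. By the rule of choice, none of these 10 peaks overlapped an Input peak. They were also the 10 highest-scoring peaks of the whole Tet3 list. Whether the peaks on chromosomes 17, 2 and 9 lie in repeated sequence, which can collect reads from many copies, was not checked, so their scores and widths do not rank them as Tet3 sites.

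Few Tet3 peaks coincided with Input peaks. In all, 2 Tet3 peaks overlapped an Input peak by at least 1 bp, a share of 0.0586% (exact binomial 95% interval 0.0071 to 0.212). Random placement of the Input peaks gave a median of 1 and a 95% range of 0 to 4 overlaps, so the observed number did not stand apart from chance. The control of each call is unknown, and overlap would be kept low by construction if one library served as control for the other. Both overlapping Tet3 peaks ranked low in their list. One lay on chromosome 17 at 28973444 to 28974677 with a score of 55.91, and the other on chromosome 6 at 146276331 to 146277819 with a score of 50.65. Within 1 kb of an Input peak there were 11 Tet3 peaks on 8 chromosomes, above the range of 0 to 6 from placement. Within 100 kb there were 166 against a range of 96 to 151. The placement kept each peak on its chromosome but not in its region.

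The 5 highest-scoring Input peaks included 3 on chromosome 8. The top one lay at 13001767 to 13002490 with a score of 95.96, and the others at 20022640 to 20023105 (84.47) and 65382695 to 65383491 (81.29). The remaining ones lay on chromosome 2 at 5494909 to 5495553 (84.98) and on chromosome 15 at 21043624 to 21043979 (81.25).

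Tet3 peaks were unevenly distributed between chromosomes. Ranked by density, chromosome 8 came first with 345 peaks or 2.71 per Mb, followed by chromosome 7 with 316 peaks (2.14 per Mb), chromosome 19 with 120 (2.06 per Mb) and chromosome 11 with 220 (1.87 per Mb). The autosome with the lowest density was chromosome 13, with 104 peaks and 0.919 per Mb. The median over the 18 autosomes other than chromosome 8 was 1.36 per Mb. Chromosome 8 held 1.996 times the number of Tet3 peaks expected from the pooled rate of those 18 autosomes (Poisson 95% interval 1.79 to 2.22, counting error only). Tet3 peaks were gathered in regions, as described below, so a Poisson interval understates the spread of their counts between chromosomes.

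The same chromosome stood further apart in Input. Of the 347 Input peaks, 122 lay on chromosome 8, a share of 35.2% (exact binomial 95% interval 30.1 to 40.4), against 10.1% (9.12 to 11.2) of Tet3 peaks. This was 9.58 times the number expected from the 18 other autosomes (7.95 to 11.4), which held between 5 and 19 Input peaks each. There were thus 2.83 Tet3 peaks per Input peak on chromosome 8 and 13.6 on the other autosomes together. Tet3 peaks on chromosome 8 were wider than those of the other autosomes, with medians of 893 bp (813 to 977) and 732 bp (721 to 742). Input peaks on chromosome 8 had a median width of 580 bp (550 to 599) against 565 bp (540 to 581), so the intervals overlapped. Of the Tet3 peaks on chromosome 8, 11.6% (exact binomial 95% interval 8.41 to 15.5) had a score that matched the genome-wide background, against 23.9% (22.4 to 25.4) on the 18 other autosomes, where single chromosomes ranged from 14.4 to 34.0%. The median score of Tet3 peaks was 69.7 (65.3 to 73.6) on chromosome 8 and 64.7 (64.4 to 65.8) on the other autosomes. These intervals overlapped, which does not show equal medians. Chromosome 8 held 12.8% (10.6 to 15.2) of the highest-scoring 25% of Tet3 peaks. Its shares of the other 25% groups, lowest scores first, were 9.50% (7.61 to 11.7), 8.32% (6.56 to 10.4) and 9.85% (7.93 to 12.0). Only the interval of 8.32% lay wholly below that of 12.8%. The lower-scoring 50% held 152 of the 345 chromosome 8 peaks, against 1543 of 3052 on the other autosomes. The matching shares above were thus not compared at equal scores. Among the lower-scoring 50% of the list the difference in matching scores was not resolved, at 20.4% (14.3 to 27.7) against 27.5% (25.3 to 29.8). In Input the corresponding shares over all peaks were 52.5% (43.2 to 61.6) and 57.3% (50.6 to 63.9), with overlapping intervals.

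The X chromosome was nearly empty in both lists. It carried 15 Tet3 peaks, 13.2 times fewer (Poisson 95% interval 8.02 to 23.6) than the 199 expected from the 18 other autosomes. The highest-scoring X-linked peak, chosen after its values were seen, lay at 135917157 to 135917684 with a score of 98.15, and the next at 7705930 to 7706924 with 83.73. Of the 15, 10 had a score that matched the genome-wide background. No Input peak lay on the X chromosome where 14.6 were expected. A count of 0 allows up to 3 peaks, or 0.865% of the list, so the X chromosome had at least 4.88-fold fewer Input peaks than expected by this one-sided limit. The upper bound of the exact Poisson interval drawn in the plot of density by chromosome is 3.69 peaks.

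**Figure D2:**
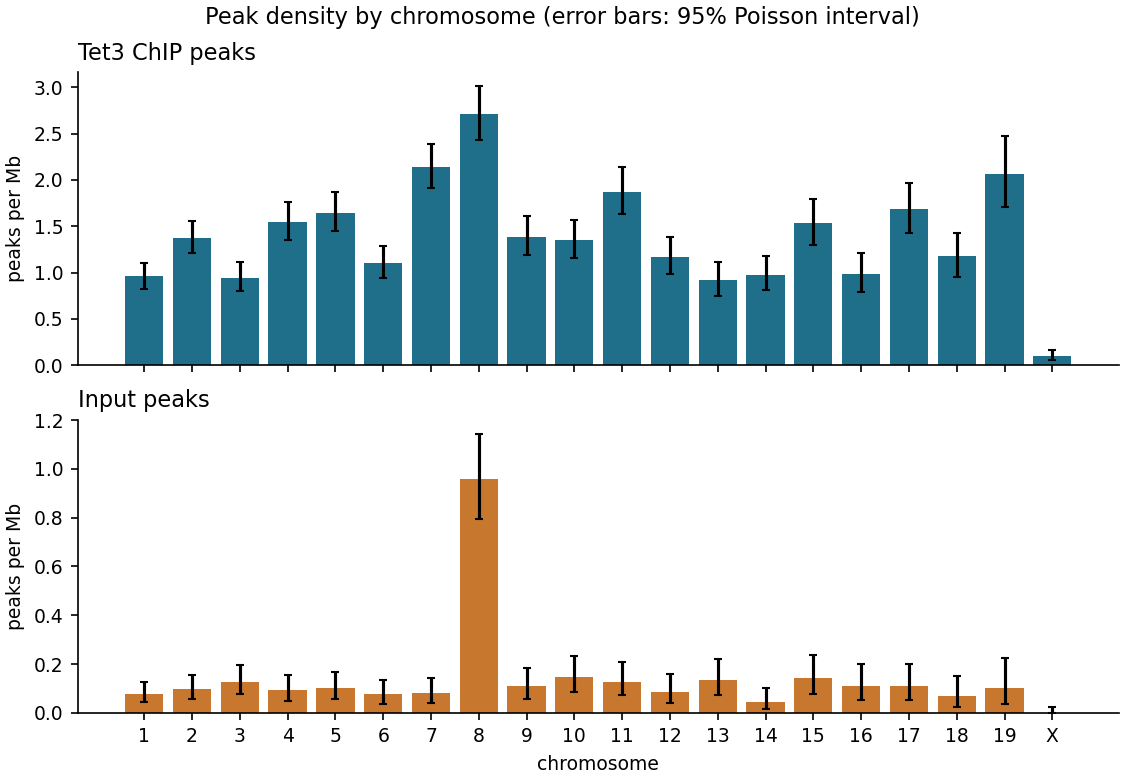
Peaks per Mb of each chromosome's span (y axis) by chromosome (x axis) for Tet3 ChIP (top) and Input (bottom), with 95% Poisson intervals of the counts as error bars. Chromosome 8 is highest in both lists, at 2.71 and 0.958 peaks per Mb, and the X chromosome lowest, at 0.103 and 0.

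Along the chromosomes, Tet3 peaks gathered in particular regions, whereas Input peaks were not detectably more gathered than under random placement. The 5 Mb window with most Tet3 peaks was 70 to 75 Mb on chromosome 8, with 46 peaks, followed by 25 to 30 Mb on chromosome 7 with 41, 120 to 125 Mb on chromosome 8 with 40 and 50 to 55 Mb on chromosome 7 with 38. The end of chromosome 4, at 150 to 155 Mb, held 36, and the adjoining windows from 75 to 80 and 80 to 85 Mb on chromosome 10 held 35 each. The median window held 5. To measure this, 5 Mb windows were counted from the first peak of each chromosome, a different grid from the windows just named. On chromosome 8 the variance of the Tet3 count per window was 8.21 times its mean, against 0.545 to 1.65 under random placement. The corresponding Input value was 1.17, within its range of 0.521 to 1.62. This ratio lies nearer to 1 in a shorter list of equal unevenness, so each value is read against its own placements only. Chromosome 7 gave 7.39 for Tet3 and 1.02 for Input, the latter within 0.607 to 1.47. Its 12 Input peaks are too few for this measure to show unevenness. Tet3 lay above the placement range on 19 of the 20 chromosomes, the exception being the X chromosome, where 15 peaks are also few for this measure. Single chromosomes other than 8 held few Input peaks, so the 18 other autosomes were also pooled. The pooled value was 4.59 for the 3052 Tet3 peaks, against 0.868 to 1.11 under placement, and 1.06 for the 225 Input peaks, against 0.866 to 1.15.

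**Figure D3:**
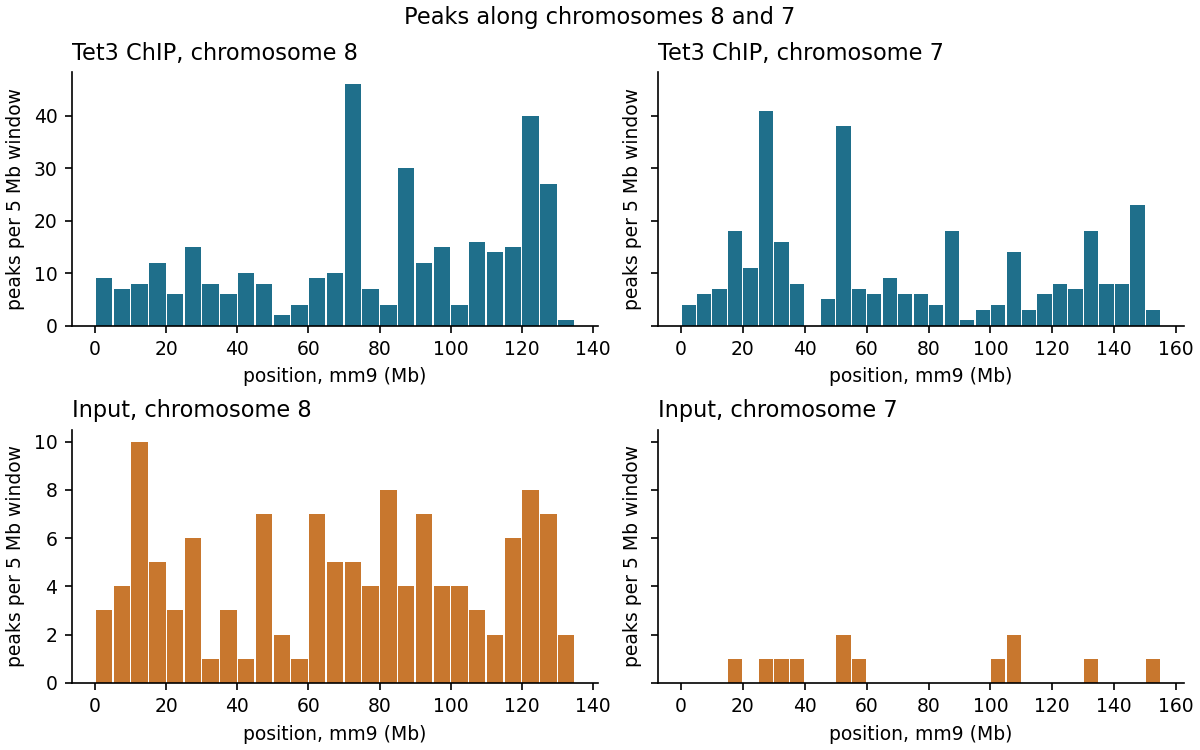
Number of peaks per 5 Mb window (y axis) along chromosomes 8 (left) and 7 (right) in mm9 coordinates (x axis, Mb) for Tet3 ChIP (top) and Input (bottom). Tet3 peaks pile up in windows such as 70 to 75 Mb of chromosome 8, with 46 peaks, while Input peaks are spread along the whole of chromosome 8 and are sparse on chromosome 7, which has 12.

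At short range, 604 Tet3 peaks, or 17.7%, lay in 271 clusters joined within 10 kb. Random placement gave a median of 114.5 clustered peaks and a range of 87 to 146. In Input 2 peaks were clustered, within the range of 0 to 8. Most Tet3 clusters were pairs, 227 of the 271. The cluster with most peaks was at the start of chromosome 9, from 2999835 to 3036760, with 10 peaks over 36.9 kb and scores from 63.3 to 289.79. The next lay on chromosome 8 at 73359310 to 73393179, inside the densest 5 Mb window, with 6 peaks scoring 57.79 to 120.5. The third was the stretch of chromosome 2 that held 3 of the highest-scoring peaks, at 98502217 to 98507665, with 4 peaks in 5.45 kb. It was tied in number with 7 others and came first among them by score. None of the 3 clusters contained an Input peak. Clustered Tet3 peaks had a median score of 67.0 and single ones of 64.6.

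**Figure D4:**
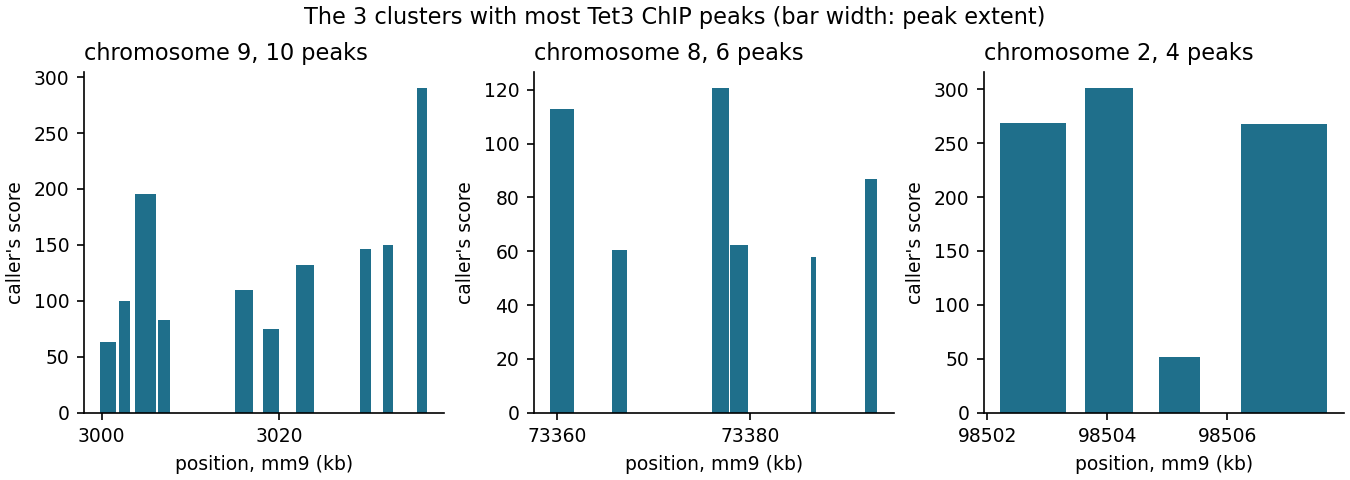
Position in mm9 (x axis, kb) and caller's score (y axis) of the Tet3 ChIP peaks in the 3 clusters with most peaks, with each bar as wide as its peak. The chromosome 9 cluster has 10 peaks over 36.9 kb, the chromosome 8 cluster 6 over 33.9 kb, and the chromosome 2 cluster 4 over 5.45 kb.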

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

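The number of peaks depends on the caller's threshold by construction: the higher-scoring 50% left 1706 Tet3 and 174 Input peaks. In that part of the lists, the median Tet3 width was 890 bp, the chromosome 8 share of Tet3 peaks 11.3% and their X share 0.234%, and 0 Tet3 peaks overlapped an Input peak. The overlap was also 0 when at least 50% of the Tet3 peak had to be covered, and 11 peaks lay within 1 kb of an Input peak. Joining peaks within 50 kb put 1156 Tet3 and 10 Input peaks in clusters, and joining within 5 kb put 0 Input peaks there. Each of these Tet3 cluster counts was above, and each Input count within, the range of random placement at the same distance, also with the 481 Tet3 peaks at 5 kb. A threshold of at least 60 on the score, added after seeing the data, left 2088 Tet3 and 89 Input peaks with median widths of 848.5 and 601 bp and 0 overlaps. The other 13 of 29 alternatives moved shares and medians within their 95% intervals and counts by less than 1.5 times. Among these, the chromosome 8 share of Input peaks was 36.2% in the higher-scoring 50%, and, in checks added after seeing the data, leaving out chromosome 8 gave 17.1% of Tet3 peaks in clusters and 2 overlaps, and leaving out the dense clusters on chromosomes 9 and 2 and the widest peak on chromosome 17 left 590 clustered Tet3 peaks. The alternatives on promoter windows, genes at promoters and gene lists were not run, since no mm9 annotation was used. No paired analysis was possible because each group has 1 library. The background rates fitted to the scores, 3.05 reads per kb for Input and 4.05 for Tet3, differ far less than the peak numbers, but how the caller scaled the libraries and their total depth are unknown, which limits what the peak numbers say about the cells.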

Other observations

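The explanations below were weighed after the chromosome counts had been seen. Only the tests of the highest-scoring 25% of Input peaks and of Input peaks inside the clusters were set out before their values were known.

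Tet3 peaks were unevenly spread over the genome at a scale larger than single clusters. The 10% of 5 Mb windows with most Tet3 peaks, 54 of 536, held 33.4% of the list, against 21.5 to 22.7% when the peaks were placed at random on their chromosomes. The 10% of windows with most Input peaks, a different set, held 53.6% of the Input list, within the 52.2 to 55.3% from placement. Placement kept the 122 Input peaks of chromosome 8 there, and 335 windows held no Input peak. For Input the comparison is therefore a weak test of evenness. In the Tet3 list 33 windows held none, 20 of them among the 31 windows of the X chromosome. Of the 10 densest windows, 4 lay on chromosome 8 and 2 on chromosome 7. On the 18 other autosomes the window counts of Tet3 and Input had a Spearman correlation of 0.085 over 460 windows, and on chromosome 8 of 0.29 over 26. Windows are not independent replicates.

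Input peaks were in excess on chromosome 8, 9.58 times the number expected from the other autosomes, and a few local regions on chromosome 8 are argued against as the source, because all 10 equal segments of the chromosome had more Input peaks per Mb (0.393 to 1.49) than the highest other autosome (0.146). Chromosome 8 also held 40.2% (exact binomial 95% interval 29.9 to 51.3) of the highest-scoring 25% of Input peaks. The excess was thus not confined to the lowest-scoring Input peaks. By the reading set beforehand, an interval above the share given by chromosome length counts against peaks that only just pass the score threshold. The interval lay above it, as length gives 17.5 of the 347 Input peaks. That reading assumes that the highest-scoring 25%, with scores from 60.12 to 95.96, lie well above the threshold. Over all Input peaks where they were recovered, the read numbers had quartiles of 9 and 11. The highest-scoring 25% may thus lie close to the threshold too, and the question is left undecided. Extra copies of the whole chromosome 8 in the cells, an aneuploidy known from cultured mouse embryonic stem cells, remain open as a hypothesis. Tet3 peaks were 1.996 times the expected number there. A Tet3 count whose Poisson 95% interval lay above the expected number was also seen on 5 other autosomes, chromosome 7 among them. Further autosomes, such as chromosomes 1 and 13, had intervals below the expected number. Because Tet3 peaks were gathered in regions, these intervals understate the spread of counts between chromosomes. The 5 raised autosomes had no such Input excess, so the Tet3 excess alone does not decide. Segments 4 and 5 of the 10, with 1.18 and 1.26 Tet3 peaks per Mb, lay below the median of the other autosomes (1.36). Tet3 density also varied within each of those autosomes, so the low segments are no evidence either way. In a model with a uniform Poisson background and no local one, a 1.5-fold read density gives 26.6 times the Input peaks. This is above the observed 9.58, which would need a 1.32-fold density. For Tet3 a 1.5-fold density gives 49.9 times the peaks, far above the observed 1.996. The model takes all peaks at the median width and holds no Tet3 binding, so 1.32 is not an estimate of copy number. Extra copies cannot be told apart from other chromosome-wide differences in read density, and the control of the Input call is unknown. The lower share of Tet3 scores that matched the genome-wide background on chromosome 8 does not separate them, since any could raise the local background. That lower share was not resolved among the lower-scoring 50% of Tet3 peaks (20.4%, interval 14.3 to 27.7, against 27.5%) or in Input.

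The X chromosome had few peaks in both lists. Complete removal of the X chromosome from the Tet3 list is excluded by its 15 peaks there. For the Input list, with 0 peaks on the X chromosome, removal is not excluded. A lower read density on the X chromosome may contribute, since 66.7% of its Tet3 scores (exact binomial 95% interval 38.4 to 88.2) matched the genome-wide background, against 23.9% on the other autosomes, and 72.7% (39.0 to 94.0) against 27.5% in the lower-scoring 50%. Fewer copies of the X chromosome, as in male cells, poorer mapping and a lower number of Tet3 sites were not separated by these values. Neither list held a peak on the Y chromosome, and it is not known whether reads were mapped to it. At a 0.5-fold read density, the uniform background model gives 0.031 Input and 0.096 Tet3 peaks on the X chromosome, against 0 and 15 seen. Since that model holds no Tet3 binding, it does not separate them either.

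Dense clusters of high-scoring Tet3 peaks lay at the start of chromosome 9 and at 98502217 to 98507665 on chromosome 2. One hypothesis is reads from high-copy sequence collected at few places of the assembly, which would mark these peaks as technical. It predicts Input signal at the same places, and 0 Input peaks lay inside the 3 clusters. This cannot be told apart from specific binding, because the control of each call is unknown and a caller that compares one library with the other would report no Input peak where both are high. The same doubt, also untested, covers the highest-scoring Tet3 peak, on chromosome 17 at 39979475 to 39985938, whose 6464 bp and score of 1552 compare with 3973 bp and 303.59 for the next widest and next highest.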
